A study of Mus musculus with 8 samples.

How the data were processed

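Single cells had been profiled from the carotid arteries and aorta of female mice aged 9 to 10 months, 8 to 9 months after tamoxifen. Per the labels, the animals carried Sm22α-driven deletion of Ubr4 (Ubr4KO) or not (Ubr4WT). Cells were sorted by tdTomato into a positive (tdTPos) and a negative (tdTNeg) gate. Each library pooled the sorted cells of 2 animals, and the 8 libraries gave 2 for each of the 4 combinations of genotype and gate. Libraries are named here by genotype, gate and replicate number, as in Ubr4KO tdTPos 2.

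The deposited expression table holds counts: raw UMI counts of 10x Genomics 3′ v3.1 libraries, for 37064 cells and 19621 genes. The deposited cell table gives the library, the authors' cluster (23 in all), a predicted cell type, UMI totals in counts, and the mitochondrial share of UMIs in percent. Per the submitters' processing notes, Cell Ranger 6.1.2, Scanpy 1.9.3, edgeR 3.42.4 and the mouse genome GRCm39 were used, without stated filters. In the deposited values the smallest total was 500 UMIs per cell, the largest mitochondrial share was 8.00%, and each gene was seen in at least 6 cells. Reads of a 3′ kit come from the end of a transcript. UMIs of Ubr4 therefore need not vanish when an upstream exon is deleted.

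Cells were grouped by the authors' clusters. A cluster entered a class when its 10 leading genes held at least as many markers of its own name as of any other type, and when the most frequent predicted type of its cells matched its name. Smooth muscle cells were SMC_1, SMC_2, SMC_3 and SMC_7. Fibroblasts were FB_1 and FB_2, endothelial cells EC_1, EC_2 and EC_4, and macrophages Mac_1 and Mac_2. SMC_4, SMC_5, SMC_6, FB_3, FB_4, FB_5, EC_3 and Mac_3, with 3580 cells (9.66%), were kept out. This rule was set after the data were seen, and all clusters of a name were tried as an alternative. The clusters Prog, TC, DC and Unk kept the authors' names. DC had Igha, Igkc and Jchain, genes of antibody-secreting cells, among its leading genes, and Unk had the mast cell proteases Mcpt4 and Cma1.

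UMIs of a class were summed per library, with at least 20 cells required. Smooth muscle cells were compared in the tdTPos gate, and fibroblasts, endothelial cells and macrophages in the tdTNeg gate, 2 libraries against 2. A further 6 fits covered Prog, DC, TC and Unk in the tdTNeg gate and fibroblasts and endothelial cells in the tdTPos gate. An interaction fit compared the genotype effect of tdTPos smooth muscle cells with that of tdTNeg fibroblasts. Each fit used edgeR 4.0.16 (TMM factors, filterByExpr with a minimum count of 10, quasi-likelihood F-test) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are UMIs scaled to a common library total (CPM); normalised CPM use the TMM factors. Errors are standard errors for log2 changes and standard deviations over 2 libraries for CPM and shares. P-values measure variation between libraries, each a pool of 2 animals, and not variation between single animals. Shares of cells were compared by a two-sided exact permutation test, whose smallest possible p with 2 libraries against 2 is 0.333.

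Before the data were examined, the comparisons, 24 gene lists, 21 lists of cell type markers, the rule for named genes and most alternatives were fixed. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and again with an estimated one, and with fry. The rule named Ubr4, then called genes with a mean of at least 10 CPM and both libraries of one genotype above both of the other: the 8 largest rises and falls in smooth muscle cells and the 5 largest elsewhere. It left out unnamed gene models. It added up to 4 members with the lowest p from each list that was called or held at least 2 called genes, the 6 lowest p values where fewer than 5 genes passed, and the 5 largest interactions each way. Fewer members are named here than the rule allowed. Where a gene is named outside it (Rnaset2a, Myh11 in fibroblasts, Trnp1 and Snhg12 outside Prog, and the genes called in several fits), it was chosen after its values were seen.

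The smooth muscle fit was tested on simulated data: in 3 draws with 200 of 14166 genes changed, it recovered 62.0% at 1.5-fold, 78.7% at 2-fold, 96.7% at 4-fold and 99.3% at 8-fold, and 2.88% of its calls were false. The simulated counts were independent between genes, with no difference in cluster makeup and no effect shared by the genes of a pool. These rates need not hold for the real libraries. Alternatives tried were RLE size factors, no filter on low counts, DESeq2 1.42.0, a replicate block, a minimum fold of 1.2, equal numbers of cells, fits without mitochondrial and ribosomal protein genes, all clusters of a name, all tdTPos cells summed, single clusters, cells without Pdgfra, Pecam1 or Ptprc UMIs, all 8 libraries in one fit, and leaving out each library. Doublet calls by Scrublet in scanpy 1.11.5 covered 244 cells (0.658%) and were not used, because 4 libraries had under 0.5%. Other computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene neighbourhoods came from a RefSeq gene table of GRCm38.p6, an earlier assembly than the authors' GRCm39, for names and order only. It placed 94.8% of the genes tested in smooth muscle cells and 99.5% in tdTPos endothelial cells, the lowest and highest of the 10 fits. Shares of SMC_1, SMC_2, SMC_3, SMC_7, FB_1, FB_2 and DC between genotypes are not reported, because genes that define these clusters differed with genotype. The results of some genes are not reported.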

Results

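Single-cell RNA sequencing of carotid and aortic cells gave 2 libraries per group, each pooling 2 female mice. Ubr4WT tdTPos 1 and 2 held 4321 and 5727 cells with medians of 13300 and 11749 UMIs per cell, and Ubr4KO tdTPos 1 and 2 held 6440 and 4266 cells with medians of 12197 and 14585. Ubr4WT tdTNeg 1 and 2 held 4369 and 4602 cells (10254 and 11143 UMIs), and Ubr4KO tdTNeg 1 and 2 held 3766 and 3573 cells (10806.5 and 10252 UMIs). The reporter tdTomato stood at 167, 151, 165 and 176 CPM in the tdTPos libraries, in that order, and at 1.82, 1.44, 2.69 and 2.77 CPM in the tdTNeg libraries. Whole-library Ubr4 was 55.4 and 55.5 CPM in Ubr4WT tdTPos 1 and 2 and 18.2 and 20.3 CPM in Ubr4KO tdTPos 1 and 2. In the tdTNeg gate it was 50.5 and 49.1 CPM in Ubr4WT and 48.2 and 47.3 CPM in Ubr4KO.

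Ubr4, a large ubiquitin ligase of the N-degron pathway and the targeted gene, fell in smooth muscle cells of the tdTPos gate from 58.3 ± 0.763 to 18.3 ± 1.33 normalised CPM (mean ± SD, n = 2 libraries per genotype). The log2 change was -1.67 ± 0.07 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.35e-05). The Ubr4KO level was 8.92% of Ubr4WT in cluster SMC_3, 20.9% in SMC_1, 27.0% in SMC_2 and 43.7% in SMC_7. Ubr4 did not pass in tdTNeg fibroblasts (log2 change -0.09 ± 0.07, adjusted p = 0.510), endothelial cells (-0.03 ± 0.15, adjusted p = 0.980) or macrophages (-0.05 ± 0.10, adjusted p = 0.813). The difference between smooth muscle cells and tdTNeg fibroblasts was itself past the threshold (-1.58 ± 0.10, edgeR interaction, adjusted p = 0.000133). In fibroblasts of the tdTPos gate Ubr4 fell from 49.1 ± 1.73 to 36.5 ± 4.48 CPM (-0.45 ± 0.12, adjusted p = 0.0490). That call was lost without Ubr4KO tdTPos 1 (adjusted p = 0.430), Ubr4KO tdTPos 2 (0.135) or Ubr4WT tdTPos 2 (0.0792). Fitted alone, cluster FB_2 of these fibroblasts had Ubr4 at -0.66 (adjusted p = 0.0183) and FB_1 at 0.01 (0.993), and with equal numbers of cells per cluster Ubr4 did not pass (-0.50, adjusted p = 0.171). The 3′ tags count transcript ends, so the remaining UMIs do not measure intact Ubr4 transcript.

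**Figure D1:**
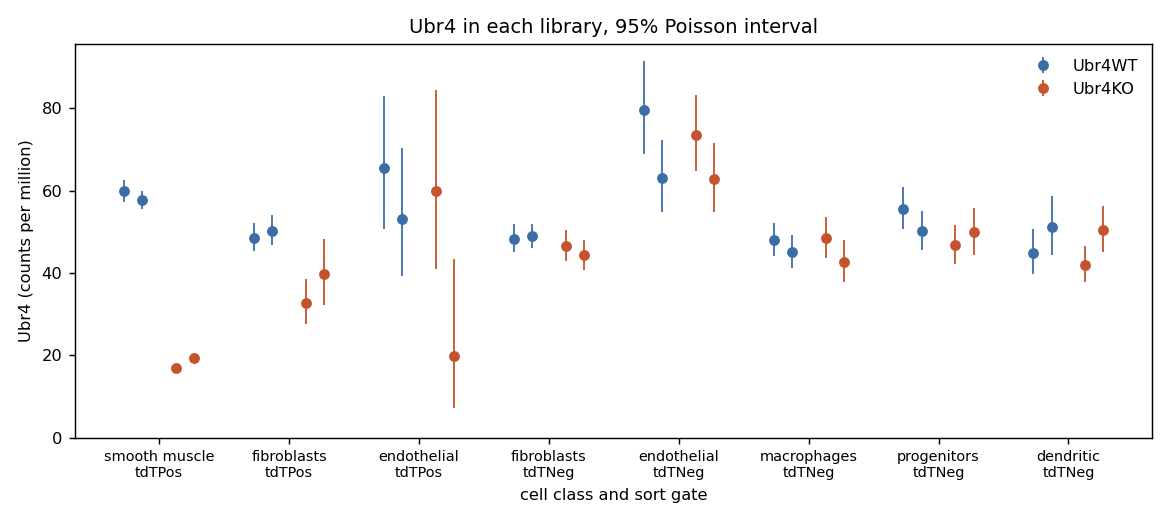
Ubr4 in CPM (vertical axis) for each library, by cell class and sort gate (horizontal axis); points are libraries, bars 95% Poisson intervals, blue Ubr4WT and orange Ubr4KO. Smooth muscle cells averaged 58.8 CPM in Ubr4WT and 18.2 CPM in Ubr4KO before TMM scaling, and tdTNeg fibroblasts 48.6 and 45.4 CPM.

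In Ubr4KO smooth muscle cells, 1159 of 14316 genes changed, 618 up and 541 down. The neighbouring transporter genes Slc22a3 and Slc22a2 both rose. Slc22a3 went from 10.7 ± 4.57 to 73.9 ± 1.78 CPM (log2 change 2.82 ± 0.21, edgeR adjusted p = 0.000219). Slc22a2 went from 11.9 ± 0.300 to 38.3 ± 5.40 CPM (1.69 ± 0.10, adjusted p = 0.000103). Further large rises were Nxph1, a secreted neurexin ligand (1.89 ± 0.12), Apoe, the lipid carrier (1.81 ± 0.16), Zbtb16, a glucocorticoid-responsive transcription factor (1.78 ± 0.35), and Mia (1.59 ± 0.18). Among genes with a mean of at least 10 CPM, the largest fall was that of the ribonuclease gene Rnaset2b, from 41.3 ± 6.80 to 1.60 ± 0.0957 CPM (-4.69 ± 0.14, adjusted p = 5.61e-07). Next among these came Sft2d1, a Golgi membrane gene, from 18.4 ± 0.688 to 2.38 ± 0.661 CPM (-2.94 ± 0.16, adjusted p = 5.95e-05). The near-identical copy Rnaset2a rose (adjusted p = 0.000950). The sum of both copies was 85.8 ± 14.1 CPM in Ubr4WT and 101 ± 17.7 CPM in Ubr4KO, so the change of either copy is uncertain. S1pr3, a sphingosine-1-phosphate receptor (-1.83 ± 0.23), Thbs1, an adhesive glycoprotein (-1.80 ± 0.14), Stc1 (-1.43 ± 0.27), the magnesium transporter Slc41a1 (-1.42 ± 0.20) and Klhl31 (-1.40 ± 0.26) also fell. Apoe and Mia are among the genes that define SMC_1, and S1pr3 and Thbs1 among those of SMC_3. Fitted within the single clusters, Apoe lay between 0.77 and 1.71, Mia between 0.85 and 1.79, S1pr3 between -2.08 and -0.34 and Thbs1 between -2.31 and -0.33. Most Ubr4WT smooth muscle cells stood in SMC_7 and SMC_2, and most Ubr4KO cells in SMC_1 and SMC_7, so the summed class differed in makeup. With equal numbers of cells per cluster 894 genes were called, and 761 of the 1159 calls (65.7%) were kept.

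Leaving out Ubr4KO tdTPos 2 left 320 calls, leaving out Ubr4KO tdTPos 1 left 599, and leaving out Ubr4WT tdTPos 2 gave 1967, with every tested call keeping its direction. Without Ubr4KO tdTPos 2 the calls of Zbtb16 (adjusted p = 0.0831), Stc1 (0.0698) and Klhl31 (0.0855) were lost. Without Ubr4WT tdTPos 2 Zbtb16 stood at 2.71, and without Ubr4WT tdTPos 1 Stc1 stood at -0.86.

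**Figure D2:**
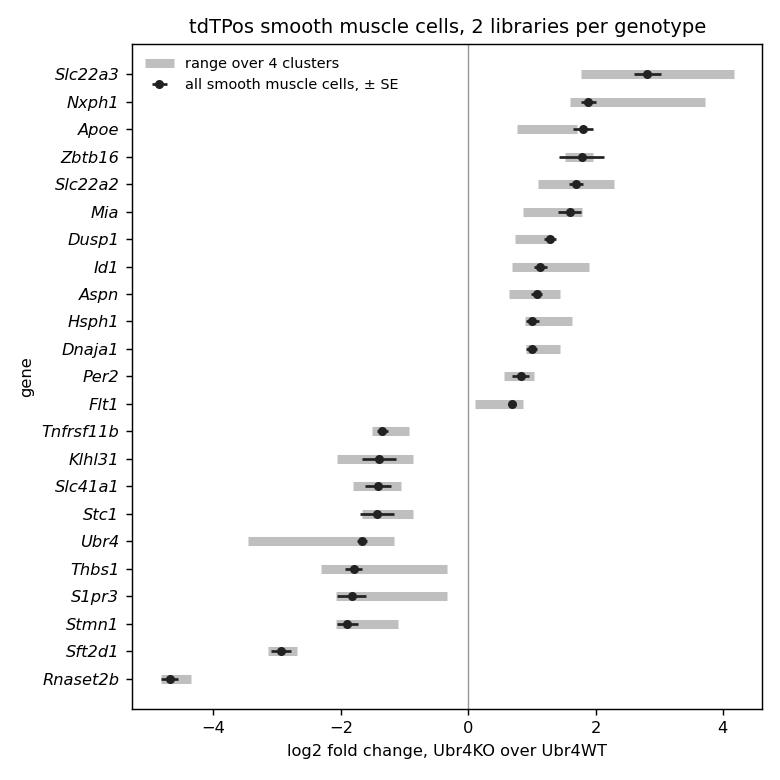
Log2 fold change of Ubr4KO over Ubr4WT (horizontal axis) for named genes (vertical axis) in tdTPos smooth muscle cells; points with bars are all smooth muscle cells ± standard error, grey bands the range over the single clusters SMC_1, SMC_2, SMC_3 and SMC_7. Values run from -4.69 for Rnaset2b to 2.82 for Slc22a3.

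Immediate early and dissociation stress genes rose as a group in Ubr4KO smooth muscle cells: 24 of the 41 measured members rose and the rest did not pass (25 rose and 1 fell adjusted over the list alone). Dusp1, a phosphatase that switches off MAP kinases, rose from 559 ± 43.4 to 1367 ± 16.4 CPM (log2 change 1.29 ± 0.09). The heat shock chaperone gene Hsph1 (1.01 ± 0.10) and the immediate early gene Ier2 (0.86 ± 0.09) rose as well. Of the 24 lists this alone was called against other genes (camera, adjusted p = 1.38e-08), also without any 1 library (highest adjusted p = 0.00283). It was not called with an estimated correlation (adjusted p = 0.919 with an estimated correlation), nor by fry (adjusted p = 0.397).

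The contractile apparatus list was not called in smooth muscle cells: 24 of 36 members were positive, 1 rose (0 adjusted over the list alone) and the median log2 change was 0.08 (camera adjusted p = 0.191). By fry without regard to direction it passed (adjusted p = 0.0193), as did 18 of the 24 lists. Myh11, the smooth muscle myosin heavy chain, averaged 3546 ± 179 CPM in Ubr4WT and 4011 ± 251 CPM in Ubr4KO before TMM scaling, and none of the 9 measured smooth muscle markers passed (median 0.01). Of 31 calcium handling and ion channel genes, 3 rose and 3 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.285). The T-type calcium channel gene Cacna1h fell from 2.91 ± 0.402 to 1.07 ± 0.195 CPM (log2 change -1.43 ± 0.21). TGF-beta and BMP response genes moved both ways, 9 of 27 up and 5 down (13 and 6 adjusted over the list alone; camera adjusted p = 0.180). Among them Id1, a BMP target, rose from 114 ± 17.7 to 250.2 ± 1.11 CPM (1.13 ± 0.10), the inhibitory Smad7 (1.01 ± 0.11) and Ccn1 (0.80 ± 0.09) rose, and Ltbp2 fell (-1.06 ± 0.11).

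Of 22 measured genes of modulated smooth muscle cells 8 fell and 4 rose (10 and 4 adjusted over the list alone; camera adjusted p = 0.148). Tnfrsf11b, which encodes osteoprotegerin, fell from 56.9 ± 7.38 to 22.4 ± 0.663 CPM (log2 change -1.35 ± 0.09, edgeR adjusted p = 0.000191). Osteopontin, Spp1, fell from 3.83 ± 1.33 to 0.409 ± 0.0225 CPM (-3.21 ± 0.29), although it stood at 1.07 within SMC_2. Lgals3, a galectin, rose (0.77 ± 0.10). Of 28 proteoglycan and matrix glycoprotein genes 5 rose and 6 fell (6 and 6 adjusted over the list alone; median 0.01, mean -0.15, camera upward with adjusted p = 0.935). Asporin, Aspn, rose (1.07 ± 0.08) and the cytokine-like Cytl1 fell (-1.68 ± 0.23; 0.40 within SMC_3). Of 18 collagens 1 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.291). Col8a1 fell (-0.87 ± 0.13) and Col1a2 rose (0.48 ± 0.09). Both collagen calls were lost without Ubr4KO tdTPos 2 (adjusted p = 0.0588 and 0.128). Of 19 elastic fibre genes 2 rose and 3 fell (4 and 4 adjusted over the list alone; median 0.03, mean -0.07, camera downward with adjusted p = 0.878). The microfibril genes Mfap4 (0.80 ± 0.08) and Mfap5 (0.73 ± 0.08) rose and Fbln2 fell (-1.49 ± 0.18). Of 20 matrix proteases and inhibitors 1 rose and 4 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.407), among them the protease inhibitor Timp4 (-0.70 ± 0.08). In the same cells 5 of 10 fibroblast markers fell and 1 rose (median log2 change -0.50), and the 7 macrophage markers measured had a median of -2.08 with 1 past the threshold. Fibroblasts made up 26.0 ± 4.44% of tdTPos cells in Ubr4WT and 5.01 ± 1.19% in Ubr4KO. Their marker Dcn went from 67.3 ± 11.0 to 37.8 ± 6.11 CPM in smooth muscle cells before TMM scaling. Less RNA from fibroblasts or macrophages is therefore not excluded as a source of falls in these lists. Cytl1, for example, is a leading gene of FB_2.

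Of 23 lipid and cholesterol genes 6 fell and 1 rose in Ubr4KO smooth muscle cells (12 and 4 adjusted over the list alone; camera adjusted p = 0.148). Those that fell included Idi1, an isoprenoid synthesis enzyme (log2 change -0.98 ± 0.10), and Sqle, squalene epoxidase (-0.73 ± 0.10). Of 32 angiogenic and growth factor genes 6 fell and 1 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.148). Angpt2 (-0.82 ± 0.10) and Igfbp2 (-1.33 ± 0.18) fell and the VEGF receptor Flt1 rose (0.69 ± 0.07). Igfbp2 is among the genes that define SMC_2 and lay between -1.67 and -0.27 within single clusters. Stmn1, a microtubule regulator, fell from 9.09 ± 1.79 to 2.45 ± 0.296 CPM (-1.89 ± 0.16). It was 1 of 2 of the 16 cell cycle genes past the threshold, both down (4 down adjusted over the list alone; camera adjusted p = 0.148). Stmn1 also fell in tdTNeg cells, whose Ubr4 did not pass: -2.04 ± 0.23 in fibroblasts (edgeR adjusted p = 0.00308) and -1.15 ± 0.09 in DC (0.00457). It did not pass in macrophages (-1.74 ± 0.22, adjusted p = 0.0547) or endothelial cells (0.01 ± 0.23, adjusted p = 0.999). Of 22 p53 and senescence genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.953). Btg2, an antiproliferative gene, rose from 1255 ± 94.7 to 2358 ± 476 CPM (0.91 ± 0.14). Of 15 circadian genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.148). The call of Per2 (0.83 ± 0.13) was lost without Ubr4KO tdTPos 2 (adjusted p = 0.0595).

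The stress response and protein turnover lists held few changes in smooth muscle cells. Of 28 unfolded protein and integrated stress response genes 3 rose (3 adjusted over the list alone; median -0.01, mean 0.21, camera upward with adjusted p = 0.935). They were Chac1, a glutathione-degrading enzyme, from 0.554 ± 0.203 to 3.62 ± 1.86 CPM (log2 change 2.67 ± 0.41; 2.01 without Ubr4KO tdTPos 1), the pseudokinase Trib3 (2.06 ± 0.36) and Herpud1 (0.41 ± 0.07). The last 2 were lost without Ubr4KO tdTPos 1 (adjusted p = 0.0588 and 0.0542). Ubr4 was the single call among 16 N-degron and UBR family genes (camera adjusted p = 0.735). Of 44 proteasome genes 1 rose (1 adjusted over the list alone; camera adjusted p = 0.148), and of 30 autophagy and lysosome genes 2 rose (2 adjusted over the list alone; median -0.03, mean 0.01, camera adjusted p = 0.935). Of 21 inflammatory mediators 5 rose and 3 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.935). Of 35 interferon and antigen presentation genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.242), and of 18 oxidative stress genes 1 fell (1 adjusted over the list alone; camera adjusted p = 0.640). Median log2 changes were -0.08 for the 13 mitochondrially encoded genes (camera adjusted p = 0.407), 0.00 for the 82 nuclear oxidative phosphorylation genes (adjusted p = 0.735) and -0.00 for the 81 ribosomal protein genes (adjusted p = 0.935).

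In tdTNeg fibroblasts, whose Ubr4 did not pass, 736 of 13369 genes changed with genotype, 422 up and 314 down. Contractile genes rose as a group: 12 of 35 measured members rose (18 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.69e-06, adjusted p = 0.850 with an estimated correlation). Acta2, smooth muscle actin, rose from 68.3 ± 3.36 to 215 ± 81.0 CPM (log2 change 1.66 ± 0.21, edgeR adjusted p = 0.00511), Tagln from 21.7 ± 3.75 to 50.8 ± 12.5 CPM (1.22 ± 0.17) and Lmod1 (0.96 ± 0.13). Of 9 smooth muscle markers 6 rose in these cells (median 1.14), and 5 of 9 macrophage markers fell (median -0.74). Other large rises were Sost, the Wnt inhibitor sclerostin (2.46 ± 0.15), Gimap6 (2.44 ± 0.12), the matricellular gene Postn (2.18 ± 0.19), and Zbtb16 (2.09 ± 0.48, adjusted p = 0.0429; 3.53 without Ubr4WT tdTNeg 2, 1.43 without Ubr4WT tdTNeg 1). Rnaset2b fell (-5.46 ± 0.10), while its sum with Rnaset2a was 317 ± 5.41 CPM in Ubr4WT and 313 ± 9.08 CPM in Ubr4KO. Other large falls were Sft2d1 (-3.34 ± 0.12), the homeobox gene Meox1 (-3.04 ± 0.29), the potassium channel Kcnk2 (-1.85 ± 0.22) and the purinergic receptor P2ry1 (-1.85 ± 0.20). The class differed in makeup between FB_1 and FB_2. With equal numbers of cells per cluster 659 genes were called, 558 of the 736 among them (75.8%). FB_1 alone gave 431 calls and FB_2 alone 737, and Sost (0.84 in FB_1), Postn (0.50) and Tagln (0.23) passed in FB_2 but not in FB_1. Leaving out Ubr4WT tdTNeg 2 gave 1282 calls.

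Elastic fibre genes rose in the same fibroblasts, 3 of 20 past the threshold (3 adjusted over the list alone; camera adjusted p = 0.00784, highest 0.0907 without 1 library, and adjusted p = 0.850 with an estimated correlation). They were elastin, Eln, from 713 ± 167 to 1519 ± 183 CPM (log2 change 1.09 ± 0.15), the crosslinking enzyme Lox (0.76 ± 0.11) and fibulin-5, Fbln5 (0.43 ± 0.06); Eln (0.50) and Fbln5 (0.17) did not pass within FB_1 alone. Calcium handling genes moved up as a list, with 4 of 26 up and 1 down (5 and 1 adjusted over the list alone; camera adjusted p = 0.00490, adjusted p = 0.847 with an estimated correlation, fry adjusted p = 0.0310). The calcium pump gene Atp2a2 was among them (0.59 ± 0.09). Circadian genes also moved up, 5 of 14 past the threshold (8 up and 3 down adjusted over the list alone; camera adjusted p = 0.0227, highest 0.0907 without 1 library, adjusted p = 0.850 with an estimated correlation). Nr1d1 rose from 77.9 ± 21.3 to 158 ± 16.4 CPM (1.02 ± 0.16), and Tef (0.80 ± 0.12; not past the threshold within FB_2) and Per3 (0.71 ± 0.12; 0.39 and not past it within FB_2) rose. Interferon genes fell, 3 of 35 past the threshold and 30 negative (6 down adjusted over the list alone; camera adjusted p = 1.88e-05, adjusted p = 0.847 with an estimated correlation). They were Ifi27l2a (-0.74 ± 0.08), Ifit3 (-0.84 ± 0.15) and Rtp4 (-0.61 ± 0.11), none past the threshold within FB_1 alone, and Ifit3 not with equal numbers of cells per cluster (adjusted p = 0.0513). Ifit3 and Rtp4 did not pass within FB_2 either. Ribosomal protein genes shifted down slightly, 76 of 81 negative with a median of -0.08 and Rps2 past the threshold (-0.35 ± 0.06, though not within FB_2; camera adjusted p = 0.000312, adjusted p = 0.850 with an estimated correlation).

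Of the fibroblast lists that were not called, collagens had 4 of 19 up and 2 down (10 and 3 adjusted over the list alone; camera adjusted p = 0.0789). Col14a1 rose (log2 change 0.53 ± 0.09) and Col8a1 fell (-1.16 ± 0.11). Proteoglycans had 3 of 28 up and 4 down (6 and 8 adjusted over the list alone; median 0.05, mean -0.05, camera adjusted p = 0.775). Thrombospondin-2, Thbs2, rose (0.69 ± 0.09) and Cytl1 fell (-0.83 ± 0.13; not past the threshold within FB_1). Immediate early genes had 5 of 40 up and 3 down (11 and 6 adjusted over the list alone; camera adjusted p = 0.677). Hsph1 (1.15 ± 0.11) and Dusp1 (0.59 ± 0.08) rose and Egr2 (-0.72 ± 0.10) and Ier2 (-0.37 ± 0.06; not past the threshold within FB_2) fell. Modulated smooth muscle genes had 1 of 21 up and 3 down (3 and 9 adjusted over the list alone; camera adjusted p = 0.148). The transcription factors Sox9 (-0.79 ± 0.08) and Tcf21 (-0.82 ± 0.14) fell and Tnfrsf11b rose (0.64 ± 0.11). Tnfrsf11b stood at -0.24 within FB_1 and did not pass within FB_2 or with equal numbers of cells per cluster (0.24, adjusted p = 0.215). Angiogenic genes had 6 of 30 up and 2 down (7 and 3 adjusted over the list alone; camera adjusted p = 0.440). The IGF-binding Igfbp4 rose (0.71 ± 0.06) and Fgf1 fell (-1.08 ± 0.13), both not past the threshold within FB_1 (0.16 and -0.63).

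In tdTNeg endothelial cells 52 of 11581 genes changed, 16 up and 36 down. Inflammatory mediators fell as a list, 4 of 27 past the threshold (10 down and 1 up adjusted over the list alone; camera adjusted p = 0.000208, adjusted p = 0.811 with an estimated correlation). The chemokine Ccl2 fell from 191 ± 34.2 to 69.5 ± 11.6 CPM (log2 change -1.47 ± 0.17), as did Cxcl2 (-1.45 ± 0.23), complement C3 (-1.82 ± 0.25; 0.34 within EC_2) and Tnf (-2.01 ± 0.30; lost without Ubr4KO tdTNeg 1, adjusted p = 0.0521). Of 9 macrophage markers 5 fell in the same cells (median -1.32), and Cd209f (-2.53 ± 0.17), Fcna (-2.08 ± 0.29) and Tgfbi (-1.29 ± 0.16) fell too. The 10 fibroblast markers had a median of -0.49, with 0 past the threshold. In cluster EC_4 53 of 283 cells were called doublets. A lower share of macrophage or fibroblast RNA or cells in this class is therefore not excluded as a source of these falls, including the inflammatory mediators. Contractile genes rose as a list, 28 of 30 positive and 2 past the threshold (2 adjusted over the list alone; camera adjusted p = 1.39e-05, adjusted p = 0.811 with an estimated correlation). Acta2 rose from 22.4 ± 19.6 to 202 ± 41.2 CPM (3.11 ± 0.43, edgeR adjusted p = 0.0344; 4.54 without Ubr4WT tdTNeg 2 and 2.47 without Ubr4WT tdTNeg 1). It did not pass by DESeq2 (adjusted p = 0.0897) or within EC_1 (2.02, adjusted p = 0.0731). Tagln rose from 25.5 ± 3.27 to 58.2 ± 10.6 CPM, a call lost without Ubr4KO tdTNeg 1 (adjusted p = 0.0644). Acta2 and Tagln were the 2 of 5 smooth muscle markers that rose (median 0.53). Circadian genes rose, 2 of 14 past the threshold (9 adjusted over the list alone; camera adjusted p = 9.95e-05, adjusted p = 0.811 with an estimated correlation), Tef (1.46 ± 0.21) and Nr1d2 (1.15 ± 0.16). Ribosomal protein genes shifted up, 74 of 81 positive with a median of 0.10 (camera adjusted p = 0.00103, highest 0.729 without 1 library, adjusted p = 0.980 with an estimated correlation). Zbtb16 rose (2.76 ± 0.43; 4.23 without Ubr4WT tdTNeg 2, 2.11 without Ubr4WT tdTNeg 1). The immunoglobulin gene Igha rose from 0.196 ± 0.277 to 20.6 ± 3.85 CPM (log2 change 6.61; 5.58 without Ubr4WT tdTNeg 2 and 9.12 without Ubr4WT tdTNeg 1). In the DC cluster of the same libraries Igha went from 1.94 ± 2.28 to 2877 ± 701 CPM, so whether endothelial cells made it is uncertain. Rnaset2b (-5.36 ± 0.22, sum with Rnaset2a 252 ± 24.6 against 231 ± 7.12 CPM) and Sft2d1 (-3.45 ± 0.18) fell. Leaving out Ubr4WT tdTNeg 2, Ubr4WT tdTNeg 1 or Ubr4KO tdTNeg 1 gave 366, 142 or 108 calls.

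In tdTNeg macrophages 31 of 12410 genes changed, 20 up and 11 down. The interferon-induced gene Ifi44l was seen with 827 UMIs in Ubr4KO (57.0 ± 8.61 CPM before TMM scaling) and 0 in Ubr4WT, at least 413-fold higher. Its neighbour Ifi44 rose (log2 change 4.29 ± 0.42; 3.68 without Ubr4WT tdTNeg 2, 5.46 without Ubr4WT tdTNeg 1, and lost without Ubr4KO tdTNeg 1, adjusted p = 0.0756). Outside macrophages Ifi44 moved both ways, at -2.05 in tdTNeg fibroblasts, 0.85 in tdTNeg endothelial cells and 1.66 in smooth muscle cells. The scavenger receptor Colec12 rose from 124 ± 20.8 to 442 ± 44.8 CPM (1.83 ± 0.14, edgeR adjusted p = 0.00993). Sh3bgrl3, from 871 ± 44.7 to 207 ± 17.7 CPM (-2.07 ± 0.10), the lymphocyte and monocyte antigen Cd52 (-2.24 ± 0.16), Rnaset2b (-5.15 ± 0.11, sum with Rnaset2a 643 ± 34.1 against 623 ± 60.2 CPM) and Sft2d1 (-3.55 ± 0.11) fell. Sh3bgrl3 lies near Ubr4 in gene order, as does Fblim1, whose falls in other classes are given below. Fblim1 also fell (-1.91 ± 0.19; lost without Ubr4KO tdTNeg 1, adjusted p = 0.0650). Leaving out Ubr4WT tdTNeg 2 or Ubr4WT tdTNeg 1 gave 347 or 47 calls, leaving out Ubr4KO tdTNeg 1 gave 15, and DESeq2 called 255.

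Contractile genes rose as a list in macrophages, with 2 of 31 past the threshold (7 adjusted over the list alone; camera adjusted p = 0.000487, adjusted p = 0.726 with an estimated correlation). They were Myh11, from 1.69 ± 1.01 to 19.3 ± 0.0581 CPM (log2 change 3.51 ± 0.33; 4.28 without Ubr4WT tdTNeg 2), and Acta2, from 12.4 ± 5.27 to 70.5 ± 17.0 CPM (2.51 ± 0.29), the 2 of 7 smooth muscle markers that rose (median 2.06). Both calls were lost without Ubr4KO tdTNeg 2 (adjusted p = 0.0521 for Myh11 and 0.0896 for Acta2) or Ubr4KO tdTNeg 1 (0.0756 and 0.0650). Nuclear oxidative phosphorylation genes were lower as a list, 78 of 81 negative with a median of -0.24 (12 down adjusted over the list alone; camera adjusted p = 6.00e-11, adjusted p = 0.726 with an estimated correlation). Uqcrb (-0.40 ± 0.08, adjusted p = 0.107) and the others did not pass over all genes. Proteasome genes were lower too (37 of 45 negative, camera adjusted p = 0.000487), as were ribosomal protein genes (71 of 83 negative, adjusted p = 0.000699) and cell cycle genes (17 of 21 negative, 4 down adjusted over the list alone, adjusted p = 0.00651). Each of these 3 had adjusted p = 0.726 with an estimated correlation. Of the matrix lists, proteoglycans (camera adjusted p = 0.00249, median -0.53), elastic fibre genes (0.0173, median -0.57), matrix proteases (0.0173, median -0.58), modulated smooth muscle genes (0.0423, median -0.43) and collagens (0.0295, median -0.35) were called downward. Each lost the call without at least 1 library (highest adjusted p = 0.0790, 0.555, 0.226, 0.189 and 0.716) and had adjusted p = 0.726 with an estimated correlation. The 10 fibroblast markers measured in macrophages moved the same way (median -0.52, 0 past the threshold). In cluster Mac_2 75 of 150 cells were called doublets, so a lower share of fibroblast RNA or cells in this class is not excluded. Immediate early genes were called upward (camera adjusted p = 0.00371, highest 0.383 without 1 library, adjusted p = 0.852 with an estimated correlation; 11 up and 1 down adjusted over the list alone).

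**Figure D3:**
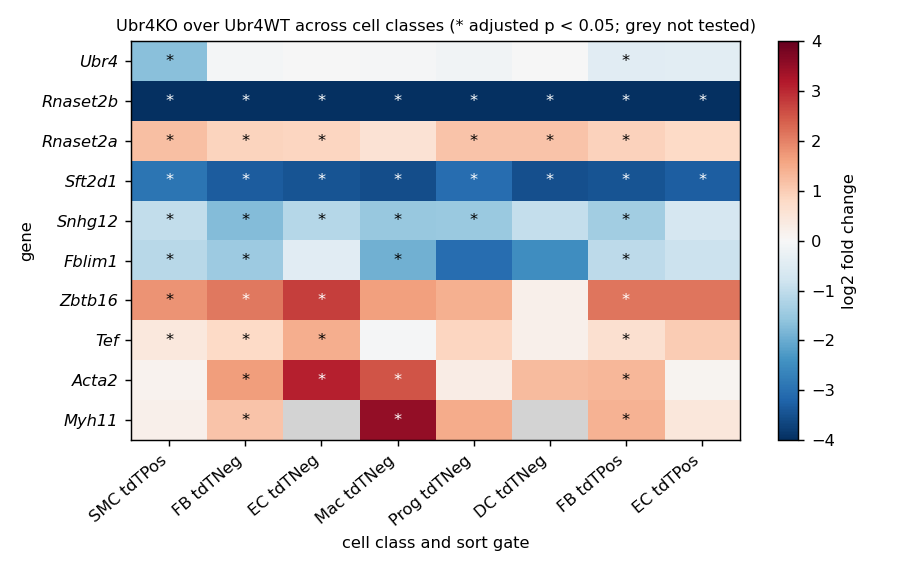
Log2 fold change of Ubr4KO over Ubr4WT (colour) for named genes (vertical axis) in each cell class and sort gate (horizontal axis); asterisks mark adjusted p under 0.05 and grey marks genes not tested. Rnaset2b lay between -5.46 and -4.44 in the 8 classes shown, and Ubr4 at -1.67 in smooth muscle cells and -0.09 in tdTNeg fibroblasts.

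The genotype effect differed between tdTPos smooth muscle cells and tdTNeg fibroblasts for 306 of 14993 genes, with 132 more positive and 174 more negative in smooth muscle cells. Besides Ubr4, Sphkap, an anchoring protein of protein kinase A, stood at 22.9 ± 3.82 and 18.5 ± 3.46 CPM in Ubr4WT and Ubr4KO smooth muscle cells but went from 0.745 ± 0.280 to 6.20 ± 0.327 CPM in fibroblasts (log2 difference -3.27 ± 0.38, edgeR interaction, adjusted p = 0.00207). Pdzrn4, a PDZ domain gene, went from 18.8 ± 2.25 to 25.6 ± 0.816 CPM in smooth muscle cells and from 2.29 ± 0.0285 to 0.601 ± 0.417 CPM in fibroblasts (2.38 ± 0.37, adjusted p = 0.010; 3.37 without Ubr4KO tdTNeg 2). The interaction count fell to 144, 175, 155, 156, 150 and 170 without Ubr4KO tdTPos 2, Ubr4KO tdTPos 1, Ubr4WT tdTNeg 2, Ubr4WT tdTNeg 1, Ubr4KO tdTNeg 2 and Ubr4KO tdTNeg 1. The classes also differ in gate, so cell type and sorting are not separated here.

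Among the other tdTNeg cells, progenitors (Prog) had 26 of 12369 genes changed, 17 up and 9 down, and Trnp1 fell from 36.1 ± 1.97 to 0.350 ± 0.0438 CPM (log2 change -6.61 ± 0.23, edgeR adjusted p = 5.57e-05). The growth factor binder Igfbp3 rose (1.74 ± 0.16; lost without Ubr4KO tdTNeg 1, adjusted p = 0.0826). The fall of Trnp1 was not limited to Prog. It also fell in smooth muscle cells (-5.48 ± 0.15, edgeR adjusted p = 5.61e-07) and tdTNeg fibroblasts (-7.61 ± 0.46, 0.000228). In tdTPos fibroblasts it fell to 0 CPM in Ubr4KO (adjusted p = 0.000333), so its fitted size there is no bound. In tdTNeg macrophages it did not pass (-2.42 ± 0.59, adjusted p = 0.1175). The DC cluster had 31 of 11303 changed, 17 up and 14 down. Ifi44l, at 22.8 ± 3.69 CPM before TMM scaling in Ubr4KO and 0 in Ubr4WT, was at least 75.2-fold higher. The mannosyltransferase-like Dpy19l3 rose from 2.85 ± 0.276 to 28.4 ± 2.23 CPM (3.33 ± 0.20) and Sfrp2, a Wnt modulator, fell (-2.53 ± 0.21). The fibroblast marker Dcn went the same way in this cluster, from 323 ± 113 to 99.0 ± 21.9 CPM before TMM scaling, so whether the cells of the cluster made Sfrp2 is uncertain. T cells (TC) had 1 of 5700 genes changed, Rnaset2b (-5.88 ± 0.38), and the mast-like cluster Unk had 9 of 1963, 3 up and 6 down. There the mast cell protease gene Prss34 stood at 294 ± 102 CPM before TMM scaling in Ubr4WT and 0 in Ubr4KO, at least 28.9-fold lower, and Sh3bgrl3 fell (-1.68 ± 0.26). Sft2d1 fell in Prog (-3.06 ± 0.15) and DC (-3.50 ± 0.14). Leaving out Ubr4WT tdTNeg 2, Ubr4WT tdTNeg 1, Ubr4KO tdTNeg 2 and Ubr4KO tdTNeg 1 gave 343, 221, 13 and 14 calls in Prog, 77, 103, 50 and 35 in DC, 9, 5, 48 and 20 in TC, and 11, 9, 3 and 17 in Unk.

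In the tdTPos gate, fibroblasts had 623 of 12615 genes changed, 404 up and 219 down. Gimap6 rose from 4.33 ± 0.367 to 30.2 ± 1.10 CPM (log2 change 2.81 ± 0.17, edgeR adjusted p = 1.08e-06), Lgals3 from 10.7 ± 0.172 to 48.4 ± 5.45 CPM (2.16 ± 0.14, adjusted p = 1.20e-06), and Sft2d1 fell (-3.44 ± 0.26; -4.59 without Ubr4KO tdTPos 1). This class also differed in makeup between FB_1 and FB_2. FB_2 alone gave 449 calls and kept 389 of the 623 (62.4%), and FB_1 alone, with 105 and 51 cells in Ubr4KO tdTPos 1 and 2, gave 30. With equal numbers of cells per cluster 234 genes were called, 202 of the 623 among them. Gimap6 and Sft2d1 passed in all 3 of these fits, and Lgals3 in FB_2 (2.05) and with equal numbers (2.16), while FB_1 held too few counts to test it. Smooth muscle transcripts were also higher in these fibroblasts, with Acta2 at 798 CPM in Ubr4WT and 1991 CPM in Ubr4KO, Tagln at 308 and 700 CPM and Myh11 at 86.0 and 223 CPM. Taken wholly as smooth muscle RNA, these levels amount to at most 11.4% of the RNA in a Ubr4KO library. Such a share would leave Sft2d1 at 25.8 CPM or more, Gimap6 at 4.25 CPM or less and Lgals3 at 20.8 CPM or less, against at most 3.43, at least 29.5 and at least 43.7 CPM before TMM scaling. It would leave Ubr4 at 45.7 and 46.0 CPM in Ubr4KO tdTPos 1 and 2, against 32.7 CPM (95% Poisson interval 27.5 to 38.5) and 39.7 CPM (32.3 to 48.2), so it is not excluded for Ubr4 in the second library. For genes abundant in smooth muscle cells it stays open. Endothelial cells there had 9 of 7769 changed, 4 up and 5 down, with the chemokine Ccl5 down from 299 ± 168 to 2.94 ± 4.16 CPM (-6.27 ± 0.64; -10.78 without Ubr4KO tdTPos 1, -5.64 without Ubr4KO tdTPos 2, -5.53 without Ubr4WT tdTPos 1). Ccl5 is a leading gene of the T cell cluster, which made up 0.0956 ± 0.0611% of Ubr4WT and 0.0234 ± 0.0332% of Ubr4KO tdTPos cells. Whether endothelial cells made it is uncertain. Leaving out Ubr4KO tdTPos 1 or Ubr4KO tdTPos 2 left 50 or 108 calls in the fibroblasts. In the endothelial cells the count was 23, 47, 3 and 34 without Ubr4WT tdTPos 2, Ubr4WT tdTPos 1, Ubr4KO tdTPos 2 and Ubr4KO tdTPos 1.

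The reporter gate of Ubr4KO held mostly smooth muscle cells. They made up 57.1 ± 9.68% of tdTPos cells in Ubr4WT and 89.9 ± 1.95% in Ubr4KO (mean ± SD, n = 2 libraries). Fibroblasts went from 26.0 ± 4.44% to 5.01 ± 1.19%, endothelial cells from 1.91 ± 0.337% to 0.779 ± 0.107% and macrophages from 0.907 ± 0.320% to 0.0778 ± 0.0437%. In the tdTNeg gate, smooth muscle cells made up 0.0904 ± 0.0664% in Ubr4WT and 1.15 ± 0.390% in Ubr4KO, endothelial cells 10.6 ± 0.0986% and 14.9 ± 0.515%, and T cells 1.07 ± 0.102% and 1.92 ± 0.545%. All of these ranges lay apart, each with the smallest two-sided exact permutation p the design allows, 0.333. Fibroblasts (34.9 ± 7.12% and 28.9 ± 2.10%), macrophages (20.6 ± 3.59% and 17.2 ± 2.06%) and progenitors (13.4 ± 1.49% and 14.5 ± 2.06%) of the tdTNeg gate overlapped (exact permutation p = 0.667). The clusters kept out of the classes (SMC_4, SMC_5, SMC_6, FB_3, FB_4, FB_5, EC_3 and Mac_3) held 12.8 ± 3.93% and 3.83 ± 0.445% of tdTPos cells and 12.9 ± 2.52% and 10.5 ± 3.72% of tdTNeg cells. With them, tdTNeg fibroblasts by the authors' names were 46.5 ± 5.42% and 34.8 ± 2.51%.

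**Figure D4:**
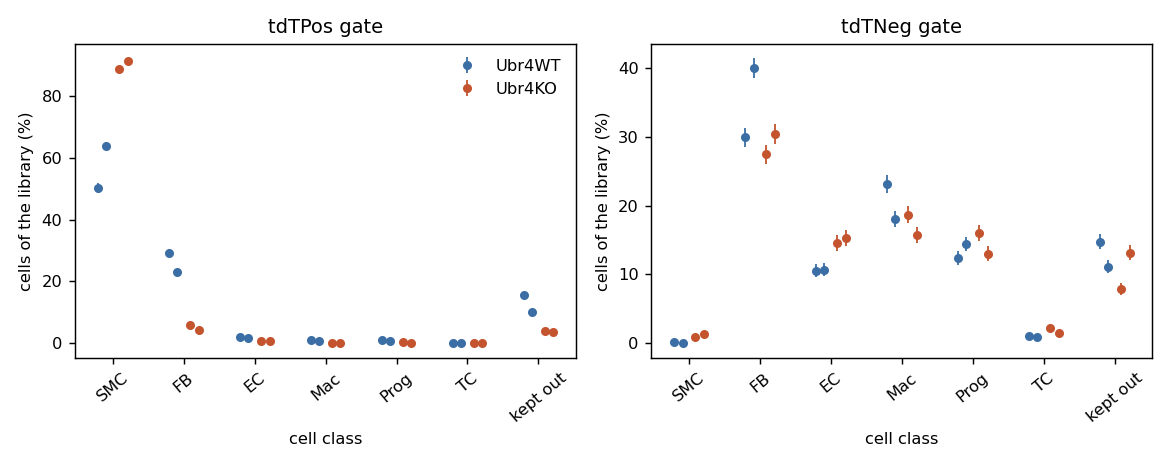
Percent of a library's cells in each class (vertical axis), by class (horizontal axis) and gate (panels); points are libraries with 95% Wilson intervals, blue Ubr4WT and orange Ubr4KO. Smooth muscle cells averaged 57.1% of tdTPos cells in Ubr4WT and 89.9% in Ubr4KO.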

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

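The tests in this part were planned, except that the share of SMC_4 was examined only after the result was seen. The genotype effect differed between tdTPos smooth muscle cells and tdTNeg fibroblasts for 306 genes by an edgeR interaction test, which is a difference between groups under the same contrast. For Ubr4 the log2 difference was -1.58. The largest differences toward smooth muscle cells were Serinc2 (4.94), Apobec2 (4.18), Gm36738 (3.05), Trib3 (2.48) and Pdzrn4 (2.38). The largest toward fibroblasts were Igfbp2 (-7.08), Efhc2 (-6.21), Apod (-3.38), Syngr3 (-3.35) and Sphkap (-3.27). Ubr4, Pdzrn4 and Sphkap passed without any 1 of the 8 libraries. The others lost the call without at least 1, with highest adjusted p values of 0.110 for Serinc2, 0.0921 for Apobec2, 0.145 for Gm36738, 0.0756 for Trib3, 0.0828 for Igfbp2, 0.171 for Efhc2, 0.177 for Apod and 0.408 for Syngr3. Several rest on few UMIs in 1 group: Serinc2 had 1 UMI in Ubr4KO fibroblasts, Igfbp2 1 in Ubr4WT fibroblasts, Apod 1 in Ubr4KO smooth muscle cells and Efhc2 0 in Ubr4WT fibroblasts, so their fitted sizes are no bounds.

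A signal also appeared in a cluster kept out of the classes. Cluster SMC_4, where haemoglobin genes outnumbered smooth muscle markers among the leading genes, made up 0.372% of cells in Ubr4KO tdTNeg 1 and 5.04% in Ubr4KO tdTNeg 2 (95% Wilson interval 4.37 to 5.80%). It made up 0.160% and 0.0869% in Ubr4WT tdTNeg 1 and 2. The excess rests on Ubr4KO tdTNeg 2, whose 180 cells had a median of 589.5 UMIs, close to the smallest total of 500. Among cells with at least 1000 UMIs, all clusters the authors named smooth muscle made up 1.69 ± 0.437% of Ubr4KO tdTNeg cells, against 4.17 ± 3.80% of all cells. In the tdTPos gate the genotypes overlapped, with 3.22% and 1.08% in Ubr4WT tdTPos 1 and 2 and 1.12% and 0.305% in Ubr4KO tdTPos 1 and 2 (exact permutation p = 0.667).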

How the results depend on the processing

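Tests on clusters chosen by leading genes, on single clusters, on all clusters of a name and on equal cells per cluster were chosen after the result was seen; the others were planned. Of 2798 values of named genes in other settings, 2461 kept direction and side of the threshold, 281 kept direction but no longer passed, 37 newly passed and 19 turned. Of 222 counts and shares, 148 stayed close to the reported value. With all tdTPos cells summed, which adds other cell types, Apoe (-1.09), Abcc9 (-0.043), Kcnj8 (-0.46), Col1a2 (-0.25), Mfap4 (-0.23) and Mfap5 (-0.63) turned negative in the smooth muscle comparison. Within single clusters Spp1 (1.07) and Nr1d1 (-0.0091) turned in SMC_2, Cytl1 (0.40) in SMC_3, Tnfrsf11b (-0.24) in FB_1, Ubr4 (0.014) in FB_1 of the tdTPos gate, and C3 (0.34) and Ubr4 (0.0025) in EC_2. Ubr4, never called in these cells, turned without 1 library and ranged from -0.17 to 0.12 in endothelial cells, -0.12 to 0.039 in macrophages, -0.12 to 0.084 in DC and -1.58 to 0.038 in tdTPos endothelial cells. For all of these the cause was not tested.

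Counts of calls moved by over 1.5 times as follows; where fewer genes or cells entered, that is part of the construction, and otherwise the cause was not tested. Without a filter on low counts there were 1934 in smooth muscle cells, 508 in endothelial cells, 355 in macrophages, 380 in Prog, 511 in DC, 50 in TC, 1011 in tdTPos fibroblasts and 99 in tdTPos endothelial cells. With a minimum fold of 1.2 there were 427 in smooth muscle cells, 252 in fibroblasts and 18 in endothelial cells. All tdTPos cells summed gave 3433, SMC_1 alone 514, SMC_2 552 and SMC_3 240, EC_1 33 and EC_2 28. FB_1 alone gave 431 in the tdTNeg and 30 in the tdTPos gate, and equal numbers of cells per cluster 234 in tdTPos fibroblasts. In macrophages DESeq2 gave 255 and equal numbers of cells 20. DESeq2 called 971 genes in smooth muscle cells, 868 of them shared with edgeR. Leaving out each library in turn gave 320 to 1967 in smooth muscle cells, 695 to 1282 in fibroblasts, 73 to 366 in endothelial cells, 15 to 347 in macrophages, 13 to 343 in Prog, 35 to 103 in DC, 5 to 48 in TC, 3 to 17 in Unk, 50 to 843 in tdTPos fibroblasts, 3 to 47 in tdTPos endothelial cells and 144 to 347 for the interaction. The lone library left in a group is assumed to vary like the others. With an estimated correlation camera called 0 lists in each of the 4 main comparisons (0 at unadjusted p under 0.05; fry called 1 in fibroblasts), against 1, 6, 4 and 11 with the preset one. Without 1 library these counts were 1 to 6, 4 to 8, 3 to 5 and 7 to 13.

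Libraries with the same number across genotypes showed correlations of residuals across genes of 0.086 in smooth muscle cells, 0.058 in fibroblasts, 0.061 in endothelial cells, 0.033 in macrophages, 0.143 in Prog and -0.104 in TC. Fibroblasts of the same number across gates correlated at 0.557 in Ubr4WT and 0.253 in Ubr4KO, and the labels do not say whether the gates share animals. The interaction fit treats all 8 libraries as independent. With a replicate block the count was 1554 in smooth muscle cells, 1195 in fibroblasts, 127 in endothelial cells, 229 in macrophages, 828 in Prog, 157 in DC, 1 in Unk, 965 in tdTPos fibroblasts, 103 in tdTPos endothelial cells and 688 for the interaction. The block changed the call of 9 of 201 named genes.

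Fits of all 8 libraries together were not run for smooth muscle cells and macrophages, and the effect of the gate on smooth muscle cells was not tested, because Ubr4WT tdTNeg 1 and 2 held 6 and 2 smooth muscle cells and Ubr4KO tdTPos 1 and 2 held 7 and 2 macrophages. Endothelial cells were fewer and shallower, with 461 and 492 cells per library in Ubr4WT at medians of 3943 and 4731 UMIs, against 2170 and 3660 smooth muscle cells at 14740 and 12664. How much this lowers their count was not simulated, and tdTPos fibroblasts gave 623 calls with 377 and 178 cells in Ubr4KO.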

Other observations

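All tests of explanations in this part were chosen after the result was seen. Genes changed in several cell types that keep Ubr4 formed a short list: 30 of 10490 genes measured in tdTNeg fibroblasts, endothelial cells and macrophages were called in at least 2 of the 3 fits, and 6 in all 3 (Rnaset2b, Sft2d1, Acta2, Igha, Snhg12 and Gm12166). Igha was far higher in the Ubr4KO DC cluster (2877 CPM), so its calls elsewhere need not arise in those cells. Gm12166, an unnamed gene model, stood at log2 changes of 4.30, 3.77 and 4.50, and Snhg12, a small nucleolar RNA host gene, at -1.74, -1.16 and -1.51. The macrophage complement genes C1qa, C1qb and C1qc fell in fibroblasts (-0.91, -0.89 and -0.85) and endothelial cells (-1.36, -1.38 and -1.32), while macrophages stood at -0.13, -0.31 and -0.16.

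In smooth muscle cells Slc22a3 and Slc22a2 lie 10 and 11 measured genes from Sft2d1 in the GRCm38 order, and Rnaset2a and Rnaset2b 4 and 9. Windows reached up to 100 measured genes to each side unless another size is given. Of the 130 genes in the window around Sft2d1, which is on another chromosome than Ubr4, 28 were called in smooth muscle cells, against a mean of 10.8 over 13579 rotations of the gene order (22 as high, 0.162%). Around Ubr4 25 of 201 were called, against a mean of 16.7 (10.1% of rotations as high). Stmn1, 62 measured genes from Ubr4, was among them. The first window was centred on Sft2d1 because that gene had changed. Its 28 calls include Sft2d1, Rnaset2a, Rnaset2b, Slc22a2 and Slc22a3, while the count around Ubr4 leaves out Ubr4. A smooth muscle count without these genes was not made, so the rotations do not test crowding apart from them.

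Genes around Ubr4 were also called in cells that keep Ubr4. In the 3 tdTNeg fits together, 32 calls lay among the 201 genes around Ubr4, against a mean of 11.8 over 10490 rotations (198 as high, 1.89%), and 26 calls with C1qa, C1qb and C1qc set aside (2.84%). The window genes called in at least 2 of these fits were Snhg12, Tmem222, Sh3bgrl3, Cep85, Fblim1 and the 3 C1q genes. Fblim1 also fell in smooth muscle cells, from 904 to 421 CPM (log2 change -1.10 ± 0.08, edgeR adjusted p = 0.000219). In tdTNeg and tdTPos fibroblasts it stood at -1.44 ± 0.08 (adjusted p = 0.000209) and -1.03 ± 0.10 (5.33e-05). In tdTNeg endothelial cells it did not pass (-0.45 ± 0.15). The other tdTNeg fits did not reach the 5% level in this window: 2 calls in Prog (7.91% of rotations as high), 3 in DC (5.82%) and 0 in TC. Around Sft2d1, the fits alone gave 18 of 127 genes in fibroblasts (1.77% of rotations as high), 5 of 122 in endothelial cells (1.13%), 2 of 129 in macrophages (6.32%), 3 of 126 in Prog (2.38%) and 4 of 129 in DC (0.994%). In TC the 1 call, Rnaset2b, lay there. With 50 or 200 genes each side macrophages had 2 (3.62%) or 5 calls (1.98%) around Sft2d1. These counts include Sft2d1 and both Rnaset2 copies where called. With these 3 genes set aside, the fibroblast, endothelial and macrophage fits together had 15 calls in the window, against a mean of 6.99 (416 of 10490 rotations as high, 3.97%). A response of Sft2d1 within the cell to its own loss of Ubr4 is argued against, since its change nearest to 0 in those fits was -3.34, against -2.94 in smooth muscle cells. Reads shared between Rnaset2a and Rnaset2b could account for the change of Rnaset2b, since the log2 ratio of their sum was at most 0.23 from 0 in the 4 types. As a hypothesis, variants linked to the targeted allele could account for calls near Ubr4, and variants near Sft2d1 that differ between the animals of both genotypes for calls there. Signals from neighbouring cells stay open and were not tested.

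Smooth muscle transcripts were higher in Ubr4KO cells outside the reporter gate. Smooth muscle RNA or cells would bring Myh11 along with Acta2, but the highest Ubr4KO library held 2.23 CPM of Myh11 in endothelial cells, against at least 27.7 predicted from Acta2, and 4.90 CPM in fibroblasts, against at least 18.2, which argues against them there. In macrophages Myh11 reached 19.5 CPM, against at least 10.3 predicted, so smooth muscle RNA or cells could account for it. The fibroblast class differed in makeup between FB_1 and FB_2, but this as the whole cause is argued against by a lowest log2 ratio of Acta2 of 0.71 over FB_1, FB_2, EC_1, EC_2 and EC_4. An effect of genotype on these cells and cells of a smooth muscle lineage without an active reporter stay open as hypotheses and were not tested.

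Fewer cells other than smooth muscle stood in the Ubr4KO reporter gate. Cells without the reporter as the whole of a class in the gate are argued against for fibroblasts and endothelial cells. The lowest tdTPos library carried 55.7 and 14.6 times the tdTomato of the highest tdTNeg one (35.9 and 5.70 at the Poisson limits). For macrophages the ratio was 7.39, but 2.50 at the Poisson limits, which leaves this open. A part of the fibroblasts or endothelial cells without the reporter is not excluded, because the ratio compares averages of whole classes. By library, tdTomato was seen in 54.6% to 73.0% of tdTPos fibroblasts and 43.3% to 56.4% of endothelial cells. In smooth muscle cells it was seen in 77.5% to 86.6%. Smooth muscle RNA or cells would bring tdTomato and Myh11 at the same percent of the smooth muscle level. In the lowest library the percent for tdTomato was 11.9 times that for Myh11 in fibroblasts and 5.39 times in endothelial cells (10.2 and 3.56 at the Poisson limits), which argues against them as the source of tdTomato there. In Ubr4WT tdTPos macrophages tdTomato stood at 9.60% and 23.6% of the smooth muscle level and Myh11 at 7.46% and 26.4%. Smooth muscle RNA or cells could account for the tdTomato of macrophages there (ratio within 1.29 times in both libraries). Dilution by more smooth muscle cells as the only cause would leave fibroblasts per endothelial cell in place. Yet these were 6.85 in the Ubr4KO library nearest to Ubr4WT, against at least 13.6 in Ubr4WT. The Ubr4KO ratios rest on 55 and 30 endothelial cells. Dilution as a part of the cause, or as the cause of the endothelial fall, is not excluded. Differences in dissection, dissociation or sorting between pools and an effect of genotype stay open as hypotheses and could not be separated with 2 pools per genotype.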
